A study of Mus musculus with 19 samples.

How the data were processed

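The samples were single-cell RNA libraries of mouse olfactory epithelium, made with a droplet method that tags each captured molecule with a unique molecular identifier (UMI). The labels describe 19 samples in 4 groups. Uninjured epithelium came from animals of 2 months (6 samples) and 18 months (6 samples). Epithelium taken 24 hours after a chemical injury with methimazole came from animals of 2 months (3 samples) and 18 months (4 samples). The samples fell into 3 batches, and most batches of a group had 2 capture channels. The labels give a yellow fluorescent source population and a sort for live cells with propidium iodide, both of which can set the shares of cell classes.

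The deposited values are UMI counts per gene and cell in 1 matrix for the whole series. Per the submitters' processing notes, the authors used Cell Ranger 3.0 and the mm10 build, and the file header of the matrix gives Cell Ranger 3.0.2. The deposited counts are whole numbers, with no normalization. The matrix held 31053 genes and 94778 cell barcodes. A number from 1 to 19 at the end of each barcode separated the libraries, but no source used here pairs a number with a sample. No group comparison was therefore made, the planned tests between ages and between injured and uninjured samples were not run, and the matrix was treated as 1 pooled sample of 19 unmapped libraries. Library numbers below are those barcode endings and carry no age or injury.

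Barcodes with fewer than 500 genes (5919) or more than 15% mitochondrial counts (11914) were left out, 15466 in all. Doublets were scored per library by the method of Scrublet, in an implementation written for these data with exact neighbours. It used 2 simulated doublets per cell and an expected rate of 0.06. Cells scoring above 0.2 were removed, which took 3581 cells (4.52% of those passing both filters). The automatic threshold of the method marked almost no cells in the libraries tried and was not used. A threshold of 0.25 was tried first, and 0.2 was set after the scores and a test with artificial doublets had been seen. In that test, 20 artificial sums per class were added to library 13, and 18 of 20 sums of a mature neuron with a neutrophil were called, 18 of 20 with an HBC, 6 of 20 with a macrophage and 4 of 20 with an immature neuron. Over libraries, 28.9% to 52.2% of the simulated doublets scored above the threshold. Doublets can therefore remain, among them those of neurons with macrophages or with other neurons. In all, 75731 cells were kept (79.9%).

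Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes were chosen, leaving out olfactory receptor genes, mitochondrial genes and those genes of the fixed lists that were not cell type markers. After scaling (capped at 10 SD), 30 principal components, 20 exact neighbours and Leiden clustering at resolution 1 gave 44 clusters. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9 were used. Cell type markers and 19 gene lists were fixed before the data were examined. A cluster was called X-like when at least 3 markers of X reached 20% of their highest cluster level and were seen in 20% of its cells. It stayed unnamed under 50 cells, with markers of another type nearly as well supported (ratio 0.75), with more markers of another type among its 10 leading genes, or when shallow with no own marker among them. These scoring rules, and an exception for a cluster led by Gucy2d and Gucy1b2, were set after the clusters had been seen. They left 15 clusters unnamed, with 7990 cells (10.6%).

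From the counts, UMIs were summed per class and library and given as CPM, a gene's share of all UMIs of the class scaled to a fixed total. No test was run and no p-value is given, since cells and unmapped libraries are not replicates of a group. Intervals are exact 95% Poisson intervals for levels and folds and exact 95% Clopper-Pearson intervals for shares, and cover counting error only. A gene was called higher or lower when it reached 10 CPM on the higher side, differed at least 2-fold, and went the same way in at least 90% of the libraries with at least 20 cells on both sides. A count under the floor of 3 UMIs was set to the floor in folds. Genes named in the text followed a rule fixed before the data were examined. For each list it took up to 4 genes with the largest fold in their highest class, among members with at least 100 UMIs, and here markers were left out. For HBC-like cells it took 10 genes up and 10 down with at least 50 CPM that were neither markers nor used for clustering. Other genes named as examples of a list were picked after their values were seen. Coordinates are from GENCODE M21 on GRCm38 (mm10), matched by Ensembl identifier.

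The class comparison was tested on simulated counts for HBC-like cells against other epithelial classes, run on 25728 genes. All 100 genes changed 4-fold and all 100 changed 3-fold were called, and 0 of 25528 unchanged genes. The simulated counts had counting error only, with no spread between libraries, free RNA or doublets. They check the calculation and give no rate of false calls in the real data. Clusters were also compared with each other inside libraries, with a ratio stratified by library (Mantel-Haenszel) over at least 3 libraries. Each gene needed 20 UMIs, and the 10 CPM minimum was added after calls at very low levels had been seen. The comparisons themselves, with a cluster chosen for its Krt6a level and another chosen for its Sprr1a level, were chosen after the clusters had been seen. Each of these was set against the HBC-like or mature neuron cluster with most cells in the libraries holding at least 20 cells of both. Alternatives covered the cell filters, doublet removal, the clustering resolution, centring components per library, library weighting, a mean over cells and leaving out each library. Total UMIs per library ran from 56476077 to 74891405.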

Results

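Olfactory epithelium renews its neurons from basal stem cells throughout life, and the labelled design sets young against old animals, uninjured or 24 hours after injury. The 19 libraries held 4484 to 5407 barcodes each. Median depth ran from 11108 to 14736 UMIs per barcode, and kept cells had a median of 13692 UMIs and 4177 genes. Because the libraries could not be tied to the samples, the values below describe the pooled cells and their spread over libraries, with no comparison of age or injury.

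Neurons made up most of the kept cells. Mature olfactory sensory neuron-like cells were 66.2% (95% interval 65.8 to 66.5) and ranged from 55.9% to 75.9% over libraries. Immature olfactory sensory neuron-like cells were 5.41% (5.25 to 5.57), with a range of 1.92% to 13.01%. HBC-like cells, named for the horizontal basal cells that act as reserve stem cells, were 3.25% (3.13 to 3.38). Globose basal cell-like (GBC-like) cells, the active progenitors, were 1.09%, and immediate neuronal precursor-like (INP-like) cells 1.36%. Sustentacular-like cells, the supporting cells of the epithelium, were 1.01% (0.939 to 1.08), and 0.559% when clustered at resolution 2. Microvillous ionocyte-like cells were 2.02%, microvillous tuft-like cells 1.48%, respiratory secretory-like cells 1.20% and Bowman gland-like cells 0.232%. Among cells of blood origin, neutrophil-like cells were 2.35% (2.24 to 2.46), monocyte-like cells 1.54% (led by the basophil genes Prss34 and Mcpt8), macrophage-like cells 0.890%, erythroid-like cells 0.438%, neutrophil precursor-like cells 0.432% and dendritic-like cells 0.314%. Olfactory ensheathing glia-like cells were 0.280%. Among the unnamed clusters, 9 and 11 (2611 and 1737 cells) matched the markers of mature and immature neurons best. Cluster 21 (737 cells) matched those of neutrophils best, cluster 31 (335 cells) B cells and cluster 35 (239 cells) T cells. Cluster 34 (267 cells) had markers of both GBCs and INPs. The shares above leave these cells out.

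**Figure D1:**
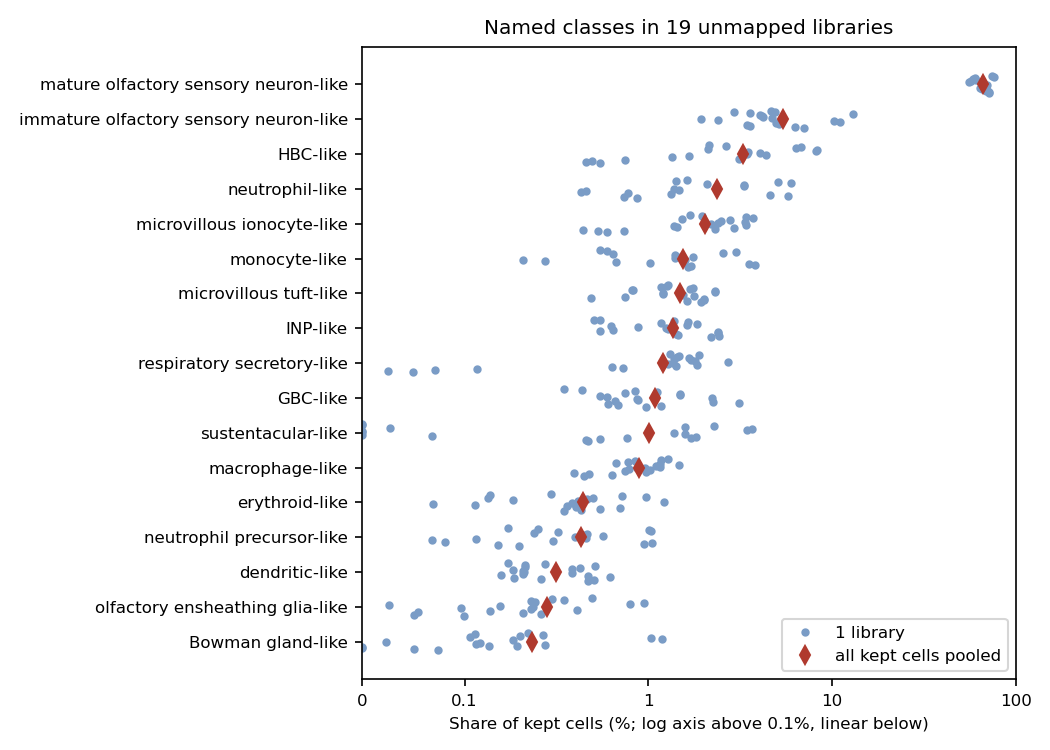
Share of kept cells in each named class, in percent on an axis that is logarithmic above 0.1% and linear below. Each blue point is 1 of 19 unmapped libraries and each red diamond the pooled share. The HBC-like share spanned 0.456% to 8.30% over libraries, and 5 libraries had no sustentacular-like cell.

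The spread over libraries was far wider than counting error for several classes. HBC-like cells ran from 0.456% in library 2 to 8.30% in library 14, with a median of 3.11%. Sustentacular-like cells ran from 0% in 5 libraries to 3.65% in library 14. Neutrophil-like cells ran from 0.431% in library 7 to 5.96% in library 16. The sort and the cell filters can set such shares, and the samples also differ in age and injury. None of these was tested, since no library is tied to a sample. Free RNA was present in every class. Omp, the mature neuron marker, gave at least 1 UMI in 52.0% of neutrophil-like cells (median 9037 UMIs) against 99.96% of mature neurons (median 13593 UMIs). Its level was 115 CPM in neutrophil-like cells and 4494 CPM in mature neurons, so levels of this kind are not read as expression.

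The fixed gene lists were described by the named class in which each member was highest, with unnamed clusters left out of that choice. Of 237 measured list genes, 190 were called higher in that class than in all other kept cells. HBC-like cells were the highest class for 40 genes (35 called), olfactory ensheathing glia-like cells for 38 (24 called), dendritic-like cells for 28 (27 called), erythroid-like cells for 23 (23 called) and macrophage-like cells for 21 (16 called). The glia-like and dendritic-like calls rest on 3 and 2 libraries with enough cells.

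Of 23 proinflammatory cytokines and chemokines 10 were highest in macrophage-like cells, and of 15 interferon response genes 11 in the glia-like class, where 5 of the 11 were called. Il1a, Il1b and Cxcl3 were among the 10 leading genes of unnamed cluster 21 (737 cells), which could not be a highest class. In macrophage-like cells the log2 fold of Cxcl3 was 6.96, and 2.00 at resolution 2. Ccl7 and Ccl2, which attract monocytes, were 1086-fold (982 to 1203) and 185-fold (179 to 191) higher in macrophage-like cells than in the rest, in 17 of 17 libraries. At resolution 2 their log2 folds were 7.83 and 5.95, against 10.09 and 7.53 here. In macrophage-like cells all 9 measured genes of NF-kappaB targets and feedback were called higher, as were all 10 of MHC class I presentation and all 6 of MHC class II presentation. Dendritic-like cells had the same counts over 2 libraries and were the highest class for 8, 8 and 6 of these genes. H2-Eb1, a class II chain, reached 9155 CPM in dendritic-like cells and 5066 CPM in macrophage-like cells. Cxcl10 (220-fold), Ifit3 (238-fold) and Isg15 (87.0-fold), all induced by interferon, were highest in olfactory ensheathing glia-like cells. These folds pool the cells of all libraries, while the direction, higher in 3 of 3, rests on libraries 13, 14 and 19. Library 7, with 18 glia-like cells, is not among these. Without it the log2 fold of Cxcl10 fell from 7.78 to 6.81. Slpi and Lcn2, antimicrobial proteins, were 85.0-fold and 61.4-fold higher in neutrophil-like cells in 18 of 18 libraries. The log2 fold of Slpi was 7.11 as a mean over cells, against 6.41 here, and that of Lcn2 6.76 at resolution 0.5, against 5.94.

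In sustentacular-like cells 12 of 14 measured genes of xenobiotic metabolism were called higher and 1 lower over 10 libraries, in respiratory secretory-like cells 13 higher and 0 lower over 15, and in HBC-like cells 10 higher and 0 lower over 18. Cyp2a5 was 137-fold (136 to 138) higher in sustentacular-like cells than in the rest, at 20627 CPM, and Cyp4b1 101-fold, in 10 of 10 libraries. With the stricter cell filters their log2 folds were 6.21 and 5.77, against 7.09 and 6.65 here. Fmo6, a flavin monooxygenase, was instead highest in HBC-like cells, 132-fold (127 to 137) above the rest in 18 of 18 libraries. All 14 S phase and 11 G2M genes were called higher in GBC-like cells over 17 libraries, and in erythroid-like and neutrophil precursor-like cells over 5 each. Monocyte-like cells had 13 and 11 higher over 17. Unnamed cluster 34 (267 cells), with markers of GBCs and INPs and the list gene Cenpf among its 10 leading genes, could not be a highest class. Among the named classes, all 14 S phase genes and 9 of 11 G2M genes were highest in erythroid-like cells. Rrm2 was at 51.5-fold and Birc5 at 38.1-fold there, in 5 of 5 libraries. As means over cells their log2 folds were 6.65 and 6.33, against 5.69 and 5.25 here. The Notch targets Hey2 (667-fold) and Hes5 (209-fold) were highest in olfactory ensheathing glia-like cells. In mature neurons 13 of 15 immediate early genes and 11 of 11 G2M genes were called lower than in the rest.

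**Figure D2:**
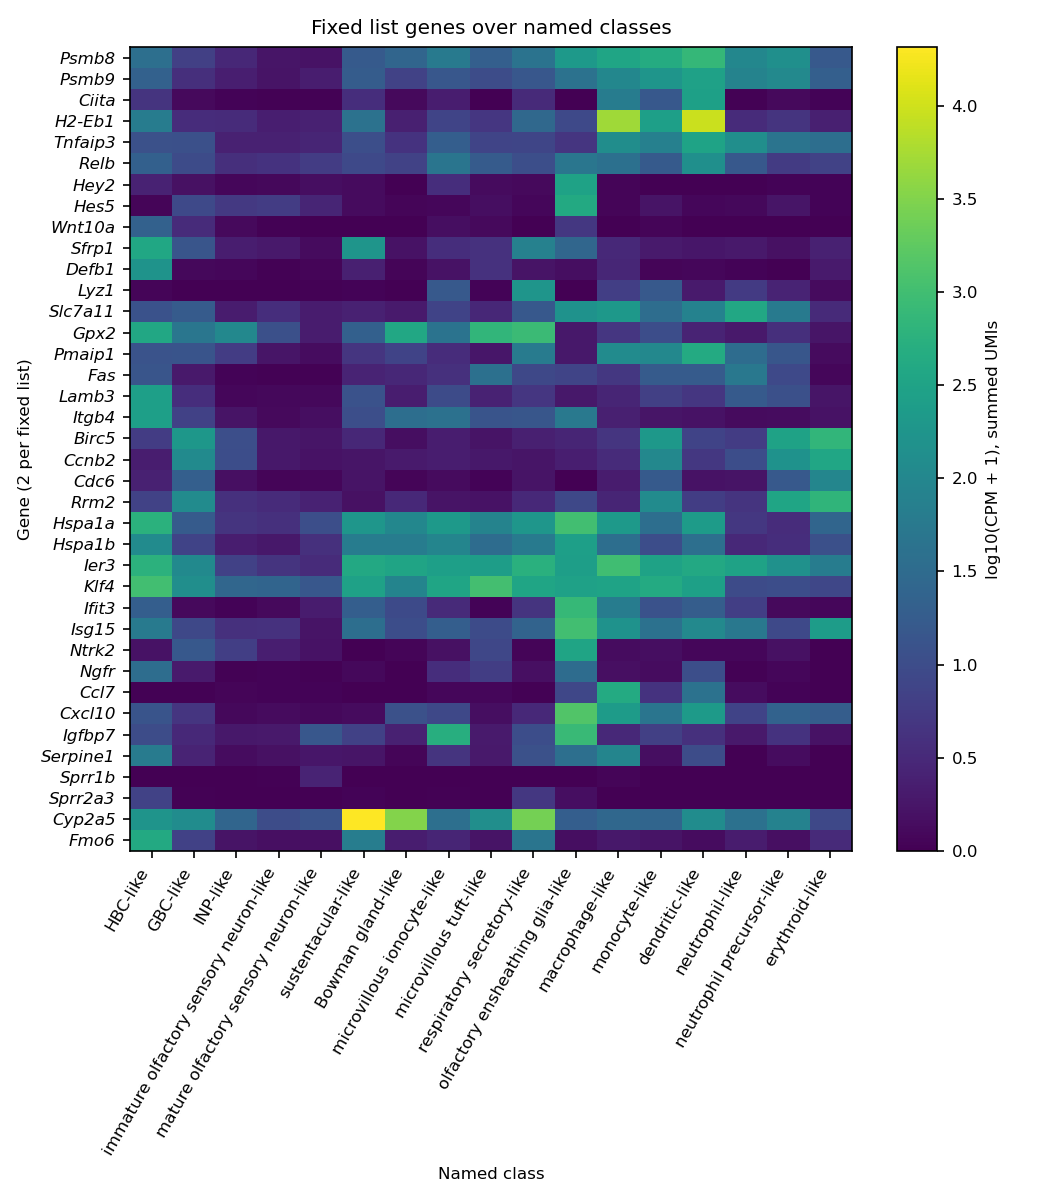
Level of 38 genes, the first 2 of each of 19 fixed lists by fold, in 17 named classes. Colour is log10(CPM + 1) of summed UMIs on the scale at the right. Cyp2a5 was highest in sustentacular-like cells at 20627 CPM.

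The comparison of HBC-like cells with the other epithelial classes asked how the class with HBC markers differs from them. It set 2464 HBC-like cells against 60548 other epithelial cells, most of which were neurons. The fixed markers held no type for basal cells of respiratory epithelium, so HBC-like cells were not told apart from these. The second best marker match was respiratory secretory for clusters 18 and 26 and sustentacular for cluster 15. Of 9811 genes that were neither markers nor used for clustering, 1578 were called higher and 3063 lower over 18 libraries. Only 228 of the higher genes also exceeded every other named epithelial class at least 2-fold. HBC-like clusters took their cells from different libraries, so these folds are averages over clusters 15, 18 and 26. Cluster 15, the largest (1089 cells), held at most 1 cell in each of libraries 7, 8, 11, 12, 15, 18 and 19. There the class was almost wholly clusters 18 and 26, so the direction counts over libraries cover different mixtures of clusters.

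The 10 genes named as higher were led by Defb1 and Dlk2. Defb1, a defensin (chromosome 8, 21776599 to 21795185), was 782-fold higher (676 to 908), at 164 CPM against 0.210 CPM. Dlk2, a Notch ligand relative (chromosome 17, 46297421 to 46303271), was 682-fold higher. Lamb3, a laminin chain of the basal lamina (chromosome 1, 193207699 to 193343878), was 346-fold higher (320 to 374), and exceeded the next epithelial class 23.5-fold. Fermt1, which activates integrins, was 527-fold higher and Col23a1, a transmembrane collagen, 609-fold. Vit, Trim29, Tns4, Slc47a1 and Axl were 521-fold, 392-fold, 342-fold, 323-fold and 315-fold higher. Each of these 10 genes went the same way in 18 of 18 libraries. Fermt1 reached a log2 fold of 9.82 as a mean over cells, against 9.04 here, and Vit 9.93 at resolution 0.5, against 9.03.

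The 10 genes named as lower were each highest in mature neurons or in INP-like cells among the other epithelial classes. The receptor genes Olfr1507 and Olfr166 were 155-fold and 103-fold lower. Receptor genes can share reads with close relatives, so these values are uncertain. Kcnmb2, a potassium channel subunit, was 82.8-fold lower, at 1.38 CPM against 114 CPM. Jakmip2 and Soga3, highest in INP-like cells, were 80.1-fold and 77.8-fold lower. Gm16579, Zbbx, Pkib, Gm42912 and Stxbp5l were 81.5-fold, 79.5-fold, 76.7-fold, 75.2-fold and 74.2-fold lower. These 10 genes went the same way in 18 of 18 libraries, at 0.391 to 2.76 CPM in HBC-like cells. Free RNA also reaches this class, where Omp stood at 74.0 CPM. Their folds shrank by over 1.5 times under at least 1 other setting, that of Olfr1507 from a log2 fold of -7.28 to -4.77 with looser cell filters.

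**Figure D3:**
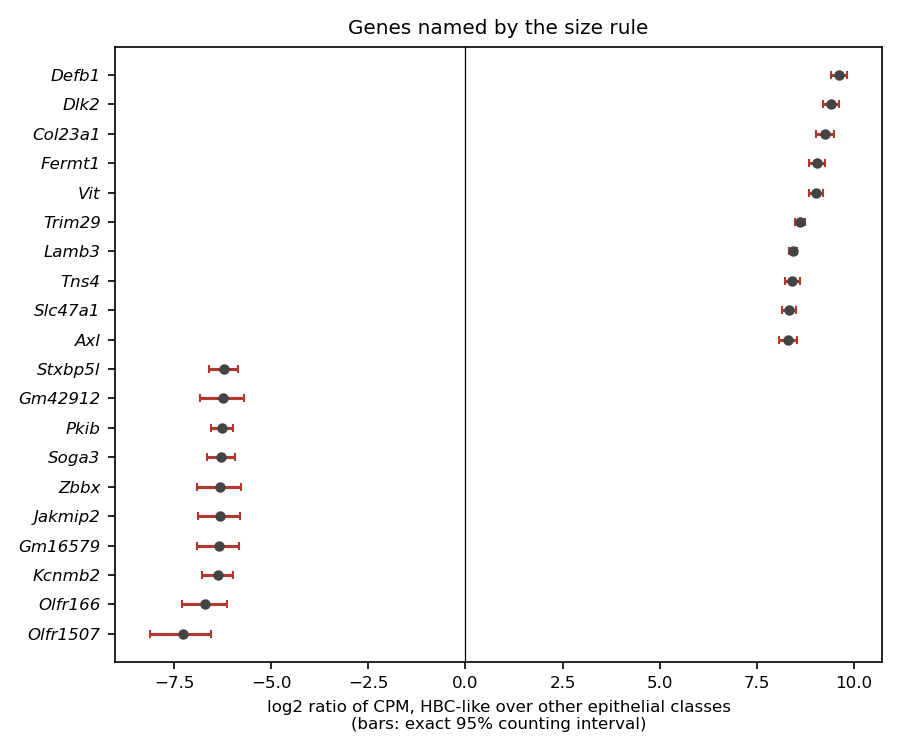
Log2 ratio of CPM in HBC-like cells over the other epithelial classes for the 20 genes named by the size rule. Points are pooled ratios and bars exact 95% counting intervals. Defb1 lies highest at 9.61 and Olfr1507 lowest at -7.28.

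Across the lists, 115 of 237 measured genes were called higher in HBC-like cells and 12 lower. These calls are against a pool that was mostly neurons, and do not place HBC-like cells above every other epithelial class. H2-D1 was at 411 CPM against 946 CPM in microvillous tuft-like cells, and Gstm1 at 2159 CPM against 5642 CPM in sustentacular-like cells. Cd74 went the other way, at 235 CPM against at most 160 CPM in another epithelial class. Free RNA or remaining doublets can also raise sums in HBC-like cells. Hbb-bs, highest in erythroid-like cells, was at 88.2 CPM there against 16.1 CPM in mature neurons, although 19.3% and 18.9% of cells held a UMI. Bpifa1, highest in respiratory secretory-like cells, was at 3946 CPM against 76.2 CPM. Obp1a was not higher, at 12.9 CPM against 19.4 CPM. How far this reaches the list calls was not tested. Of 11 basal lamina adhesion genes 10 were higher, Itgb4 by 108-fold. Of 15 immediate early genes 14 were higher, among them Junb (11.7-fold) and Fos (5.28-fold). Microvillous tuft-like cells held as much of both, with Fos at 5061 CPM against 4496 CPM in HBC-like cells. Such genes can be induced by tissue dissociation. Of 14 neurotrophin and growth factor receptors 10 were higher, with Ngfr at 140-fold and Egfr at 52.8-fold. MHC class I presentation had 9 of 10 higher and MHC class II presentation 4 of 6. Of 14 xenobiotic genes 9 were higher, of 13 Wnt pathway genes 7, and of 13 Notch pathway genes 6. NF-kappaB targets and feedback had 7 of 9 higher. The secreted Wnt inhibitor Sfrp1 was 74.5-fold higher and Wnt4 75.8-fold.

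Of 23 proinflammatory cytokines and chemokines 5 were higher and 1 lower, with Ccl20 at 68.0-fold. Interferon response had 5 of 15 higher and 2 lower. Antioxidant response had 5 of 13 higher and 2 lower, and Nqo1 was 5.39-fold lower. Apoptosis had 5 of 13 higher and 2 lower. Wound and stress epithelium had 5 of 15 higher and 2 lower, and heat shock and unfolded protein 4 of 10 higher and 3 lower. Senescence and SASP had 4 of 11 higher, antimicrobial 3 of 8, and cell cycle S 3 of 14. None of 11 cell cycle G2M genes was called in either direction.

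**Figure D4:**
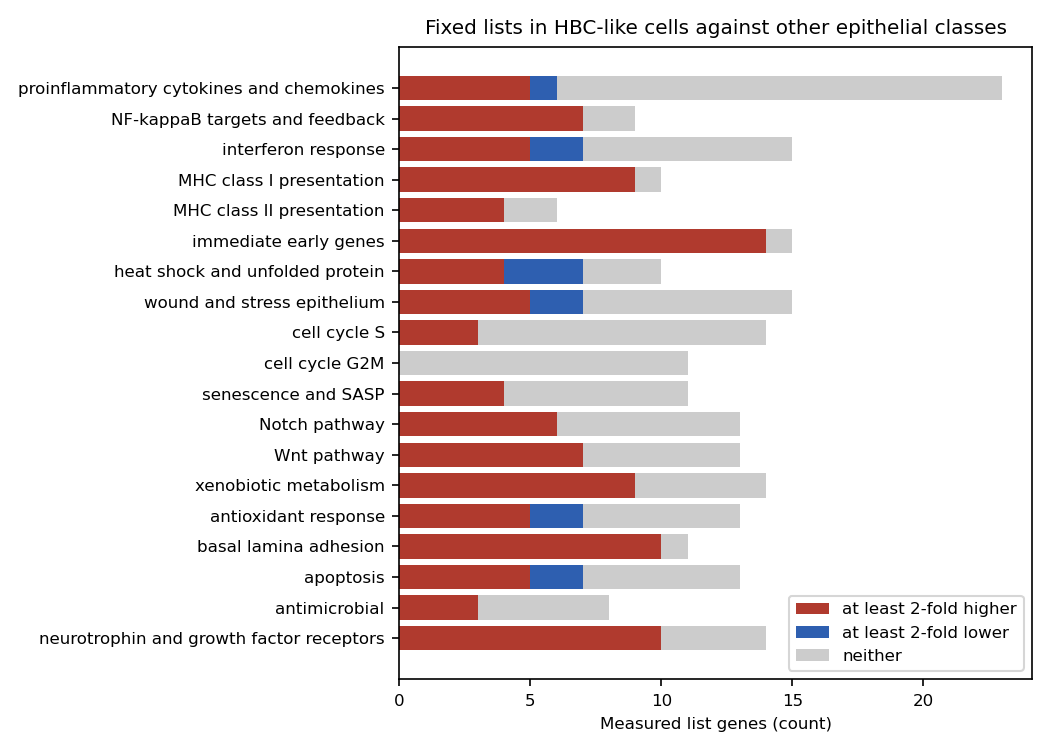
Number of measured genes per fixed list called higher (red), lower (blue) or neither (grey) in HBC-like cells against other epithelial classes. Immediate early genes had 14 of 15 higher.

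Clusters with HBC markers also differed from each other inside libraries. Cluster 15, led by Car12 and Abca4, was set against cluster 18, led by Ccdc3 and Serpina3n, in 8 libraries. Of 204 list genes 9 were higher in cluster 15 and 21 lower. The class II genes H2-Eb1 (3.02-fold) and Cd74 (2.85-fold) were higher in cluster 15. The lower genes included Lgals3, a galectin, at 2.61 CPM against 268 CPM (105-fold), S100a6 (14.3-fold) and Il33, an alarmin (15.8-fold). Each of these went the same way in 8 of 8 libraries. Against cluster 26, led by Krt15, 30 genes were higher in cluster 15 and 31 lower over 5 libraries. Lgals3, S100a6 and Il33 were again lower, but 1 of 6 class II genes was called higher, and neither H2-Eb1 (1.85-fold) nor Cd74 (1.71-fold) was. Cluster 18 had 13 genes higher and 14 lower than cluster 26 over 11 libraries.

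Cluster 23, an unnamed cluster with Krt5 and Krt14 and the highest level of Krt6a, a keratin of wounded epithelium, was set against cluster 18 in 10 libraries. Of 215 list genes 47 were lower in cluster 23 and 18 higher. The lower genes included 10 of 15 immediate early genes, such as Egr1 (3.60-fold) and Junb (3.24-fold), and 7 of 13 xenobiotic genes, such as Fmo2 (11.7-fold). The higher genes included 9 of 14 S phase genes, such as Mcm3 (3.70-fold) and Mcm2 (3.06-fold). Each of these went the same way in at least 9 of 10 libraries. Against cluster 26 only 2 genes were higher and 41 lower, and against cluster 15 (3 libraries) only 1 higher and 35 lower. Of the S phase genes, 0 of 14 were called higher against cluster 26 and 1 of 13 against cluster 15. Of 15 immediate early genes, 12 and 3 were lower against these clusters. Only libraries 10, 13 and 14 held enough cells of clusters 23 and 15. There cluster 23 had medians of 819, 1568 and 1845 UMIs and no Krt6a UMI, so no cell with Krt6a was compared. Against cluster 26 (9 libraries) the direction rule needed every library, while 9 of 10 were enough against cluster 18. The S phase counts against these comparators therefore cannot be set side by side. Cluster 23 was mixed. Its cells in library 14 had a median of 1845 UMIs and no Krt6a UMI, which allows up to 26.8 CPM, while those in library 15 had a median of 55720 UMIs and 489 CPM. Libraries 7 and 8 had medians of 1206 and 1357 UMIs with 618 and 358 CPM over their summed UMIs, which a few deep cells can carry. The count of higher genes ran from 1 to 46 over other settings. It also fell from 18 to 2 without library 7, 8, 11, 12, 15 or 19 and to 3 without library 18. It fell to 5 without library 13, to 8 without library 14 and to 9 without library 10. With 1 of the 10 libraries left out, a gene had to go the same way in all 9 others. These falls can therefore come from the stricter rule, and do not show that the calls depend on a given library.

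Cluster 3 of the mature neurons, chosen for its level of Sprr1a, was set against cluster 2 in libraries 7, 8, 11, 12, 15, 18 and 19, which held 635 to 1254 of its cells each, against at most 4 in any other library. Of 215 list genes 9 were higher and 1 lower, and the choice of cluster favoured a higher call of Sprr1a. Besides Sprr1a itself (222 CPM against 7.55 CPM), the oxidative stress gene Srxn1 was 4.40-fold higher, Atf3 2.74-fold, Ddit3 2.54-fold and Gdf15 2.47-fold, while Nqo1 was 5.27-fold lower. Each of these went the same way in 7 of 7 libraries. At resolution 0.5 only 4 genes were higher, and the lower call of Nqo1 was absent under both other cell filters and the higher doublet threshold. Against the 5 other clusters compared, 7 to 17 genes were higher and 0 to 4 lower. Srxn1 and Ddit3 were called higher against all 5. Atf3 was not called against clusters 4 (1.62-fold) and 8 (1.68-fold), nor Gdf15 against cluster 8, where it was higher in 3 of 7 libraries. Nqo1 was called lower against only 1 of these 5, cluster 5. It was 1.87-fold lower than in cluster 4, and lower in 6 of 7 libraries against clusters 0, 1 and 8.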

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

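Of the tests in this part, the ratio of shared barcodes was chosen after the result was seen.

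No comparison reads the barcode sequences, although the 2126 kept cells whose barcode recurred in any other library stayed in. Counted over all barcodes, kept or not, the 21 pairs among libraries 13 to 19 shared a median of 158 (134 to 185). The 150 other pairs shared a median of 7 (1 to 14). The ratio of these medians, 22.6, argues against chance reuse between independent captures at the rate of the other pairs. It cannot tell whether independent captures reused barcodes at a higher rate in these libraries, so chance reuse as such stays open. Reads of 1 cell assigned to another library may contribute. Only 38 of the shared barcodes, a small part of them, had a leading olfactory receptor gene (at least 3 UMIs) in both copies. The test does not reach the rest. The gene was the same in 5 of the 38 (13.2%), against 0.256% of 8605 random pairs. This lies between the levels set beforehand for reassigned reads and for their absence and leaves that explanation open. The larger copy held a median of only 1.25 times the UMIs of the smaller, nearer in size than a few stray reads would give. That size ratio was not taken for random pairs. No biological explanation was tested.

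The unnamed cluster led by Gucy2d and Gucy1b2, guanylate cyclase genes of specialised olfactory neurons, held 444 cells outside the named classes. It had cells in 19 of 19 libraries, from 8 to 47 each.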

How the results depend on the processing

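The higher doublet threshold, the repeated barcodes left out and the Krt6a cluster counted as HBC-like were chosen after seeing the data. Counts of genes and list genes higher or lower in HBC-like cells, and of list genes called in their highest class, stayed within 1.5 times under every alternative run and with each library left out. Cell shares moved beyond counting error. With at least 200 genes and at most 25% mitochondrial counts, HBC-like cells were 3.59%, mature neurons 55.3%, immature neurons 4.79%, sustentacular-like cells 1.30%, neutrophil-like cells 2.21% and the highest HBC-like share in a library 9.99%. With at least 1000 genes and at most 10%, these were 3.08%, 69.1%, 8.04%, 1.09%, 2.60% and 6.90%. With doublets kept, HBC-like cells were 3.12%, mature neurons 65.7%, immature neurons 5.64% and neutrophil-like cells 3.38%. With the higher threshold, HBC-like cells were 3.56%, the highest library share 9.81% and immature neurons 5.76%. Resolution 2 gave 63.9% mature, 6.39% immature and 0.559% sustentacular-like cells, and resolution 0.5 gave 2.78% neutrophil-like cells and named no sustentacular-like cluster. Components centred per library gave 61.2% mature and 6.45% immature neurons. Without repeated barcodes, mature neurons were 66.5%, and 30 of 76 list gene folds moved with direction kept. With the Krt6a cluster counted in, HBC-like cells were 4.11% and at most 9.86% of a library. With each library left out, the ranges were 2.99% to 3.42% (HBC-like), 65.6% to 66.7% (mature), 5.02% to 5.62% (immature), 0.870% to 1.07% (sustentacular-like) and 2.15% to 2.47% (neutrophil-like). The 18 list genes higher in the Krt6a cluster became 1 at resolution 0.5, 44 at resolution 2 and 3 with centred components. They became 46 and 43 with the looser and stricter filters, 42 with doublets kept and 43 with the higher threshold. With each library left out they ran from 2 to 18. Without 1 of the libraries compared, the direction rule needed every remaining library, so the smaller of these counts can come from that rule. For the Sprr1a cluster, 9 higher genes became 4 at resolution 0.5, and the 1 lower gene became 0 under both filters and the higher threshold. Centred components gave no value for that pair. Fosl1 in olfactory ensheathing glia-like cells turned to a log2 fold of -0.83 with libraries weighted equally. For these results the cause was not tested. Of the values of genes named for HBC-like cells, 165 stayed within their counting interval and 55 moved with direction kept, and with each library left out 380 of 380 stayed within it. Of those of list genes, 514 stayed and 316 moved with direction kept, besides Fosl1, and with each library left out 1039 stayed and 405 moved with direction kept. The settings for comparisons between groups were not run. These were DESeq2 size factors, no filter on low counts, each channel as a replicate, batch number as a block, leaving out each batch, and doublets kept in those comparisons. No paired analysis was possible because no source used here pairs a library with a sample. Depth limits classes of few cells, with 2 libraries holding enough dendritic-like cells.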

Other observations

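The 4 genes of the Mup and Obp tests were picked after the cluster had been seen, and the tests themselves were set before their result was seen. Sprr1a, a gene of stressed epithelium and injured neurons, varied widely between the unmapped libraries. In libraries 7, 8, 11, 12, 15, 18 and 19 it was at 60.3, 65.7, 70.1, 52.8, 54.5, 65.9 and 76.5 CPM, in that order. In libraries 1 to 6, 9, 10, 13, 14, 16 and 17 it was at 1.26, 1.10, 0.90, 0.993, 1.69, 1.59, 0.776, 0.654, 2.58, 3.55, 3.76 and 6.45 CPM. Krt6a was at 5.29, 6.15, 25.3, 17.1, 31.7, 9.66 and 8.63 CPM in the first of these sets, and at most 0.635 CPM (library 17) in any other library. Cyp2g1, a sustentacular enzyme, was at 4.11, 1.10, 0.942, 0.604, 1.35, 0.617 and 0.961 CPM in the first set and at 17.4, 30.4, 14.7, 38.8, 154, 165, 165, 119, 537, 610, 162 and 227 CPM in the others, in the same orders. The values of Sprr1a and Cyp2g1 fall into 2 separate clusters of libraries. No age or injury is assigned to a library from them, and no comparison of the clusters was made.

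Cluster sizes also varied. Cluster 24, a microvillous ionocyte-like cluster led by Cck and Myl9, held 62, 58, 91, 127, 57, 84 and 68 cells in libraries 7, 8, 11, 12, 15, 18 and 19 and at most 6 in any other. Cluster 17, the other ionocyte-like cluster, led by Coch and Ascl3, held at most 2 cells in those libraries, and HBC-like cluster 15 at most 1.

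Mup and Obp transcripts, which encode secreted lipocalins, led cluster 12 of the mature neurons, and 1443 of its 1630 cells came from library 13. Free RNA from another cell type is a candidate explanation, tested with the 4 genes Mup4, Mup5, Obp1a and Obp1b. In neutrophil-like cells of library 13 their summed level was 183% of that in its mature neurons (336 CPM against 183 CPM), which goes with free RNA. The highest of macrophage-like, tuft-like and HBC-like cells reached 140% of the neuronal level, which argues against a change of the neurons alone. The 4 genes were picked from the cluster's leading genes, and where the RNA came from was not tested. Obp1a was at 5086 CPM in Bowman gland-like cells and at most 501 CPM in any other named class (monocyte-like cells). Over libraries it was higher in library 14 (617 CPM) than in library 13 (186 CPM), while Mup4 was at 4.26 CPM in library 14 and 269 CPM in library 13.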
